A study of Mus musculus with 3 samples.

How the data were processed

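The data are RNA sequencing counts of 3 heart samples of wild-type C57BL/6J mice at postnatal day 9, with replicate numbers 1 to 3 in the labels. Per the labels, total RNA was extracted with Trizol and sequenced from DNBSEQ libraries. The labels do not say whether each heart came from a separate litter or animal, so p-values measure only the spread between these samples, which may be technical. All samples belong to 1 group, and every comparison is therefore between genes within a heart, or of the spread between hearts.

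The deposited table holds read counts per gene for each heart, per the file headers, and their totals differ between hearts. In each heart 87.5% to 87.6% of genes had a count within 0.005 of a whole number. The rest had fractional counts, which arise when a read that matches several genes or transcripts is divided between them, so the deposited values were taken here to be expected counts. The same table gives FPKM per gene and heart, computed by the authors, per the file headers. HISAT, an aligner, and the genome build GRCm38.p6 are named in the submitters' processing notes with no version. The counting tool, the FPKM tool, the annotation, the read layout and the strand setting are not given in the sources used here. Without a stated strand setting, reads of overlapping genes on opposite strands cannot be told apart. The table lists 18038 genes, all marked as mRNA, of which 596 had 0 counts in every heart. One further line holds annotation text spilled over from the gene above it and no value, and was left out. The 2 columns of the authors' means over the hearts were not used. Gene symbols of 25 lines had been turned into dates by a spreadsheet, and 6 lines shared a symbol with another gene ID. None of these is named in the text. Positions are those of the table. Of its gene IDs, 17911 are in the RefSeq table of GRCm38.p6, 9884 with the same start.

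Abundance was expressed as TPM, the deposited FPKM rescaled to a total of 1000000 in each heart, and as CPM, counts scaled to 1000000. Gene lengths for ratios were those implied by the authors' count and FPKM of each gene. A gene was called detected at 1 CPM or more in every heart. Levels are means ± SD over 3 hearts. Library totals were 17766501, 18643408 and 18768094 counts, and the 10 highest genes of each heart held 10.4% to 10.9% of its counts. A count of 0 allows a true level of up to 3 counts, which corresponded to 0.113, 0.109 and 0.105 TPM for a typical gene with over 100 counts. Such limits cover counting error only. To test whether a library had been deposited under 2 names, counts of each pair of hearts were compared by chi-square. The statistic per degree of freedom was 14.6, 23.7 and 9.70, so each heart was counted as a separate sample.

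Before the data were examined, 30 gene lists (534 entries), 58 gene pairs and 3 sums of genes were fixed. The lists cover tubulin glutamylases and partners, deglutamylases, other tubulin modifiers, tubulins, microtubule-associated genes, connexins and pannexins, intercalated disc genes, ion channels and calcium handling, sarcomere genes, oxidative phosphorylation, fatty acid use, glycolysis, proliferation, immediate early and heat shock genes, and hypoxia and injury. They also cover markers of endothelium, fibroblasts, smooth muscle and pericytes, macrophages and myeloid cells, lymphocytes, erythroid cells, epicardium and mesothelium, nerve and glia, and adipocytes. The rest are atrial and conduction genes, genes of thymus, lung, liver and skeletal muscle, genes of other organs as background, sex-linked genes, imprinted growth genes and mitochondrially encoded genes. Of the list entries, 36 had no match by symbol, including the mitochondrially encoded genes and Xist, and are not analysed here. The text names every glutamylase, deglutamylase and detected tubulin, the 4 members of each other list with the highest mean TPM, list members that passed the test of variation, the 10 genes with the highest mean TPM, every pair tested and the 10 variable genes with the smallest adjusted p, except for some that are not reported here. Other genes named were chosen after their values were seen: Mki67, Myc and Myh8 in the report, and in the closing section the airway genes, the receptor genes related to Esr1 and the variable genes outside the lists.

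Gene pairs were tested with edgeR 4.0.16 (R 4.3.3, limma 3.58.1). Expected counts were rounded to whole numbers, each pair gave 6 columns (2 genes in 3 hearts), and the offset was the TMM-scaled library size times the gene length. The quasi-likelihood test was run with the heart as a block, two-sided, with Benjamini-Hochberg adjustment over the 57 pairs tested and a threshold of 0.05. The pair of Igf2 and H19 was not tested. Ratios of summed TPM have no test, because an exact sign-flip test of 3 hearts cannot go below 0.25. TMM factors were 1.02, 0.997 and 0.986. Variation between hearts was tested with the edgeR goodness of fit statistic, the deviance of each gene from a single mean given the dispersion trend, in 13519 genes that passed filterByExpr. The common biological coefficient of variation was 0.119. This filter and the detection rule leave out genes present in 1 heart alone, such as Scgb1a1. For lists with at least 5 tested members (25 lists), the median deviance was compared with 10000 random lists drawn from 20 abundance bins, two-sided, with Benjamini-Hochberg adjustment. Genes of a list vary together and are not independent replicates, so these p-values are smaller than independent genes would give. They describe these 3 hearts.

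Each test was run on data with known changes. Counts for genes and pairs were simulated with the observed means, library sizes and dispersion trend, so recovery holds only as far as that trend does. The list test was run on lists of randomly drawn genes with independently simulated deviances, which were multiplied by 4 in the changed lists. For variable genes (13389 genes), 56% of 2-fold and 93% of 4-fold changes in 1 heart were recovered, with 3 unchanged genes called. For gene pairs (199 pairs), 3% were called at a true log2 ratio of 0, 90% at 1 and 100% at 2. All genes of the simulated pairs were given the same known length. These rates therefore hold no error from gene lengths, on which ratios of the real pairs also depend. For list variability (13519 genes), 5 of 5 changed lists and 0 of 20 unchanged lists were called. Genes varied independently in that run, so it gives no rate of false calls for lists whose genes vary together.

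Alternatives were leaving out each heart, other detection minimums (10 counts, 0.5 CPM), DESeq2 1.42.0 size factors and Wald test, limma on log2(TPM + 1), no heart block, both genes of a pair at 10 counts or more, no length correction, the length of the longest GENCODE M21 transcript, no filter, a filter of 10 counts, a common dispersion, Poisson deviance, and the mean in place of the median deviance. Tables were handled with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.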

Results

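RNA sequencing counts were analysed for 3 hearts of wild-type C57BL/6J mice, a standard inbred laboratory strain, at postnatal day 9. The 3 samples form the only group, so they were not compared with a second condition. They are called hearts 1, 2 and 3 after their replicate numbers. The study concerns glutamylated microtubules, microtubules whose tubulin tails carry added glutamate chains, and the coupling of cardiomyocytes. The data were therefore used to ask which tubulin-modifying enzymes, tubulins and cell junction genes the young heart expresses, in what proportions, and which genes differ between hearts. Total counts per heart were 17766501, 18643408 and 18768094. A level of at least 1 CPM (counts scaled to a library total of 1000000) in every heart was found for 12958 of 18038 genes, and 3 counts corresponded to about 0.105 to 0.113 TPM (length-scaled abundance, with a total of 1000000 per heart) for a typical gene. Spearman correlations across genes were 0.989 between hearts 1 and 2, 0.988 between hearts 1 and 3, and 0.994 between hearts 2 and 3. Heart 1 differed from the other hearts in a lung airway gene: Scgb1a1, the main secretory protein of airway club cells, had 4096 counts in heart 1, 1 in heart 2 and 13 in heart 3.

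Genes of the cardiac contractile apparatus were the most abundant in the table. Myl2, the ventricular regulatory light chain, reached 26128 ± 998 TPM (SD, n = 3 throughout), Actc1, the cardiac actin, 20958 ± 2984 TPM, and Tpm1, a tropomyosin, 13921 ± 2366 TPM. Tnnt2, Myh6, Myl3, Tnni3 and Tnnc1 followed at 12910 ± 1549, 12281 ± 318, 9700 ± 440, 7086 ± 313 and 6513 ± 491 TPM. The only genes among the 10 highest from outside the sarcomere were Mb, the oxygen-binding myoglobin, at 11736 ± 1340 TPM, and Fabp3, a fatty acid carrier, at 11085 ± 539 TPM. The 10 genes together held 13.2% of all TPM, and the 26 sarcomere genes, all detected, held 12.6%.

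Among tubulin glutamylases, Ttll1 was the most abundant transcript at 51.8 ± 3.64 TPM. Ttll1 is the catalytic subunit of a multiprotein polyglutamylase, and its gene (Entrez gene ID 319953) lies on chromosome 15 from 83483769 to 83518919 on the minus strand of GRCm38. The genes for subunits or partners of that complex were also detected: Nicn1 at 26.6 ± 2.09, Tpgs1 at 25.9 ± 2.30, Tpgs2 at 11.99 ± 0.373 and Lrrc49 at 9.00 ± 0.721 TPM. Ttll5 (ID 320244, chromosome 12, 85824920 to 86053760, plus strand) was at 10.3 ± 1.60 TPM and Ttll4 (ID 67534, chromosome 1, 74661645 to 74703730, plus strand), which starts glutamate chains, at 9.21 ± 0.498 TPM. Ttll7 and Ttll11 were detected at lower levels, 1.54 ± 0.130 and 1.47 ± 0.107 TPM. Ttll13, Ttll6 and Ttll9 fell below the detection minimum at 0.228 ± 0.118, 0.170 ± 0.209 and 0.0850 ± 0.0627 TPM. The 3 hearts held 12, 1 and 2 counts of Ttll6.

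Deglutamylases, the carboxypeptidases that remove glutamates from tubulin, were led by Agtpbp1 (ID 67269, chromosome 13, 59446198 to 59557366, minus strand) at 19.5 ± 2.70 TPM. Agbl5 (ID 231093, chromosome 5, 30888492 to 30906666, plus strand), which removes branching glutamates, reached 11.9 ± 1.61 TPM. Agbl3 and Agbl2 were at 5.39 ± 0.701 and 1.59 ± 0.388 TPM, and Agbl4 and Agbl1 were below the detection minimum at 0.257 ± 0.180 and 0.0259 ± 0.0224 TPM. Summed over each family, glutamylases exceeded deglutamylases by a log2 ratio of 0.95 ± 0.106 (74.8 ± 1.85 against 38.7 ± 2.65 TPM). Ttll1 alone was at 51.8 TPM, and the other glutamylases together were below the deglutamylases, so the sign of this ratio rests on Ttll1. Glutamylases that start chains (Ttll4, Ttll5 and Ttll7) exceeded those that extend them (Ttll6, Ttll11 and Ttll13) by 3.49 ± 0.219. Ttll1, the most abundant glutamylase, and Ttll9 were on neither side of this ratio, so it does not cover the whole family. The sums were 21.0 ± 1.83 and 1.87 ± 0.22 TPM, and of the extending genes only Ttll11 was detected. An exact sign-flip test of 3 hearts cannot fall below p = 0.25, so these sums carry no test. The log2 ratios without a length correction were 0.47 and 4.48.

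**Figure D1:**
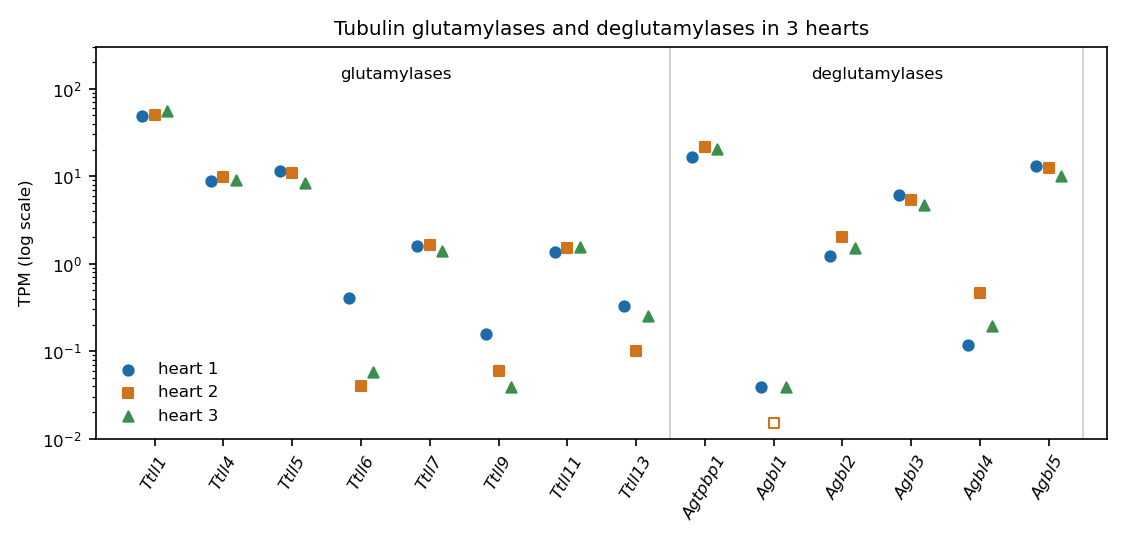
TPM (log scale) of the 8 tubulin glutamylases and 6 deglutamylases in each of the 3 hearts, with an open symbol at the base for a value of 0. Ttll1 was the highest glutamylase (51.8 ± 3.64 TPM) and Agtpbp1 the highest deglutamylase (19.5 ± 2.70 TPM).

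Pairs of these enzymes were compared within each heart with the edgeR quasi-likelihood test, with adjustment over all 57 gene pairs tested. Ttll1 exceeded Ttll5 by a log2 ratio of 2.34 (SE 0.168, edgeR adjusted p = 9.12e-05) and Ttll7 by 5.07 (SE 0.136, edgeR adjusted p = 6.05e-06), in 3 of 3 hearts each. Ttll5 exceeded Ttll7 by 2.73, whereas Ttll4 and Ttll5 did not differ beyond the spread between hearts (log2 ratio -0.15, 95% interval -0.53 to 0.24, edgeR adjusted p = 0.375). Agtpbp1 was below Ttll1 (log2 ratio -1.42, SE 0.123, edgeR adjusted p = 0.000198) and above Agbl5 (0.71, SE 0.165, edgeR adjusted p = 0.0103). Agbl5 and Ttll5 were not distinguished (0.22, 95% interval -0.08 to 0.52, edgeR adjusted p = 0.123), but passed the threshold with longest transcript lengths (0.41, edgeR adjusted p = 0.0195). Ttll6 was below Ttll4 by -5.78 and Agbl4 below Agbl5 by -5.51. Both ratios rest on genes below the detection minimum, with 12, 1 and 2 counts of Ttll6 and 2, 8 and 3 of Agbl4 in hearts 1, 2 and 3. Their size is therefore uncertain, and most Ttll6 counts came from heart 1, the heart with the Scgb1a1 counts. Tpgs1 exceeded Tpgs2 by 1.11. The lengths used matter here: without a length correction the ratio of Agtpbp1 to Ttll1 was 0.33, that of Tpgs1 to Tpgs2 was -0.70 and that of Ttll4 to Ttll5 was 0.72 (edgeR adjusted p = 0.00682, past the threshold). Agtpbp1 against Agbl5 was past the threshold neither with longest transcript lengths (0.27, edgeR adjusted p = 0.179) nor without heart 2 (0.66, edgeR adjusted p = 0.0733).

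Other tubulin modifiers were led by the deacetylase Sirt2 at 120 ± 7.93 TPM, and 9 of 12 such genes in the table were detected. Among enzymes of the tyrosination cycle, Svbp, the cofactor of the vasohibins, was at 52.3 ± 2.83 TPM, and the detyrosinating enzyme Vash1 was at 42.4 ± 6.07 TPM. Vash1 exceeded its paralog Vash2 (log2 ratio 2.12, SE 0.231, edgeR adjusted p = 0.000495) and also exceeded Ttl, the ligase that restores tyrosine (1.54, SE 0.138, edgeR adjusted p = 0.000216). Svbp exceeded Ttl by 1.85, a ratio that turned to -0.94 without a length correction. The tubulin acetylase gene Atat1 (24.4 ± 1.82 TPM) and the deacetylase gene Hdac6 (21.3 ± 3.28 TPM) were not distinguished (-0.21, 95% interval -0.56 to 0.15, edgeR adjusted p = 0.208). That pair passed the threshold with Atat1 higher under longest transcript lengths (-0.83, edgeR adjusted p = 0.00259) and without heart 1 (-0.33, edgeR adjusted p = 0.0293), and with Hdac6 higher without a length correction (0.48, edgeR adjusted p = 0.0213).

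Of 20 tubulin genes, 15 were detected. Tuba1b (ID 22143, chromosome 15, 98931427 to 98934560, minus strand) was the highest alpha tubulin at 954 ± 36.9 TPM, ahead of Tuba1a at 492 ± 49.7, Tuba4a at 324 ± 39.6, Tuba8 at 87.1 ± 39.6 and Tuba1c at 80.8 ± 11.8 TPM. Each of Tuba1a, Tuba4a and Tuba8 was below Tuba1b, with log2 ratios of -0.96, -1.57 and -3.56 (largest edgeR adjusted p = 0.000841). Tubb5 (ID 22154, chromosome 17, 35833920 to 35838301, minus strand) was the highest beta tubulin at 428 ± 20.2 TPM, above Tubb4b at 313 ± 23.2 TPM (log2 ratio 0.45, SE 0.0764, edgeR adjusted p = 0.00292). Tubb6, Tubb2a, Tubb2b and Tubb4a were at 89.8 ± 6.32, 79.9 ± 17.6, 26.9 ± 6.87 and 22.9 ± 5.98 TPM. The neuronal form Tubb3 was at 4.13 ± 0.904 TPM, below Tubb5 by a log2 ratio of 6.70 for Tubb5 over Tubb3. Tubb6 was below Tubb5 by -2.25 and Tubb2a above Tubb2b by 1.58. Gamma tubulin Tubg1 was at 52.5 ± 2.01 TPM, Tubd1 at 9.36 ± 0.883 and Tube1 at 2.06 ± 0.276 TPM. Alpha tubulins summed to 1938 ± 97.5 TPM and beta tubulins to 966 ± 36.2 TPM, a log2 ratio of 1.00 ± 0.0720 (0.68 without a length correction). Counts of the Tuba1 genes, Tuba4a, Tubb2a and Tubb2b were not whole numbers, so part of their reads was divided between near-identical genes and their split is uncertain.

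All 30 microtubule-associated, plus-end and motor genes were detected. The highest were Map7d1 at 225 ± 16.4, Stmn1, a tubulin-sequestering protein gene, at 218 ± 30.5, Map4 at 172 ± 6.56 and Clasp1 at 140 ± 13.1 TPM. Clasp1 exceeded Clasp2 by 2.60, the ubiquitous kinesin Kif5b exceeded the neuronal Kif5a by 5.61, and Map4 exceeded the neuronal Map1b by 3.56, all log2 ratios with edgeR adjusted p of 1.44e-05 or lower. Among plus-end binding genes, Mapre1 was below Mapre2 by -1.22 (edgeR adjusted p = 6.97e-05) and not distinguished from Mapre3 (0.07, SE 0.105, 95% interval -0.20 to 0.34, edgeR adjusted p = 0.537). Mapre1 passed Mapre3 with longest transcript lengths (0.50, edgeR adjusted p = 0.00687) and without a length correction (2.09, edgeR adjusted p = 2.97e-05).

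Connexins form the channels of gap junctions. Gja1, which encodes connexin 43, the main ventricular gap junction protein (ID 14609, chromosome 10, 56377300 to 56390419, plus strand), was at 400 ± 23.6 TPM. It exceeded Gja5 (ID 14613, chromosome 3, 97032402 to 97092785, plus strand), of atria and conduction tissue, by a log2 ratio of 3.23 (SE 0.163, edgeR adjusted p = 2.62e-05). It exceeded Gjc1 (ID 14615, chromosome 11, 102799472 to 102819686, minus strand) by 2.54 (SE 0.0985, edgeR adjusted p = 1.25e-05). Gjc1 and Gja5 were at 69.2 ± 8.85 and 43.7 ± 13.0 TPM, and the ratio of Gja5 to Gjc1 was -0.69 (SE 0.151, edgeR adjusted p = 0.00778). The call was lost without a length correction (-0.07, edgeR adjusted p = 0.653) and with longest transcript lengths (-0.18, edgeR adjusted p = 0.307). It was also lost without heart 2 (-0.60, edgeR adjusted p = 0.0714), where the test held fewer samples. With the gene lengths used for these ratios, Gja5 was below Gjc1 in every heart. Gja3 was at 29.4 ± 1.80 TPM, and 8 of 20 connexin and pannexin genes were detected.

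All 24 intercalated disc adhesion genes were detected, with Ldb3 at 845 ± 23.4, Popdc2 at 644 ± 65.6, the catenin gene Ctnna1 at 574 ± 37.6 and Ctnnb1 at 339 ± 29.2 TPM as the highest. The cardiac catenin gene Ctnna3 was below Ctnna1 by -5.16 (SE 0.141, edgeR adjusted p = 6.05e-06). The desmosomal genes Pkp2 and Dsg2 exceeded Pkp4 and Dsc2 by 0.32 (edgeR adjusted p = 0.0240) and 0.54 (edgeR adjusted p = 0.0409). N-cadherin Cdh2 and the endothelial cadherin Cdh5 were not distinguished (-0.17, SE 0.119, 95% interval -0.48 to 0.14, edgeR adjusted p = 0.224). Pkp2 against Pkp4 was -0.30 without a length correction and lost the call without heart 3 (0.28, edgeR adjusted p = 0.0982), and Dsg2 against Dsc2 lost it without heart 2 (0.59, edgeR adjusted p = 0.103).

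Of 33 ion channel and calcium handling genes, 32 were detected. Atp2a2, the calcium pump of the cardiac sarcoplasmic reticulum, was at 4968 ± 514 TPM, its inhibitor Pln at 4237 ± 360, the calcium store protein gene Casq2 at 968 ± 62.3 and Sln at 458 ± 25.7 TPM. Atp2a2 exceeded the fast skeletal muscle form Atp2a1 by a log2 ratio of 12.92 (SE 0.229, 95% interval 12.32 to 13.52, edgeR adjusted p = 3.42e-06), the largest of the 57 ratios. The cardiac ryanodine receptor Ryr2 exceeded the skeletal Ryr1 by 12.74 (SE 0.506, 95% interval 11.42 to 14.06, edgeR adjusted p = 1.25e-05), with 0, 4 and 6 counts of Ryr1 in the 3 hearts. Pln exceeded Sln by 3.21. Kcnj2 exceeded Kcnj12 by 0.49 (edgeR adjusted p = 0.0231). This call ended without heart 2 (0.42, edgeR adjusted p = 0.187) and without heart 3 (0.41, edgeR adjusted p = 0.110), and the ratio was -0.29 with longest transcript lengths.

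Sarcomere paralogs whose balance shifts during heart development were compared the same way. The adult myosin Myh6 (ID 17888, chromosome 14, 54941921 to 54968017) exceeded the fetal Myh7 (ID 140781, chromosome 14, 54970684 to 54994549) by a log2 ratio of 8.86 (SE 0.615, 95% interval 7.26 to 10.46, edgeR adjusted p = 8.07e-05). Counts of both genes were not whole numbers, so part of their reads was divided and the level of Myh7 is uncertain. Actc1 exceeded the skeletal actin Acta1 by 8.38 (SE 0.555, edgeR adjusted p = 6.97e-05). The adult cardiac troponin Tnni3 exceeded the fetal and slow skeletal Tnni1 by 3.01 (SE 0.435, edgeR adjusted p = 0.00151), with Tnni1 still at 1012 ± 652 TPM. The ventricular light chains Myl2 and Myl3 exceeded the atrial Myl7 and Myl4 by 3.08 and 2.67. Nppa exceeded Nppb, both natriuretic peptide genes, by 4.56, and Ckm exceeded Ckb by 4.31.

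Nuclear genes of oxidative phosphorylation were all detected (24 of 24), with Atp5b at 5798 ± 44.2, Slc25a4 at 5697 ± 259, Cox6a2 at 3777 ± 403 and Cox4i1 at 3419 ± 165 TPM. The muscle forms Cox6a2, Cox7a1 and Cox8b exceeded the ubiquitous Cox6a1, Cox7a2 and Cox8a by log2 ratios of 2.30, 0.87 and 0.67 (largest edgeR adjusted p = 0.00111), and Slc25a4 exceeded Slc25a5 by 2.79. All 20 fatty acid genes were detected, led by Fabp3, Acadl (1284 ± 41.7 TPM), Hadhb (1223 ± 45.0 TPM) and Hadha (997 ± 74.5 TPM), and the muscle Cpt1b exceeded the liver-type Cpt1a by 2.71. All 20 glycolysis genes were detected, led by Gapdh (6321 ± 615 TPM), Aldoa (2975 ± 206 TPM), Ldhb (1606 ± 16.0 TPM) and Eno3 (1320 ± 50.9 TPM). Eno3 exceeded Eno1 by 1.53, Pgam2 exceeded Pgam1 by 2.71, Ldhb exceeded Ldha by 0.60, and the insulin-responsive glucose transporter Slc2a4 exceeded Slc2a1 by 3.16. In contrast to these muscle forms, hexokinase Hk2 was below Hk1 by -1.14 (SE 0.0789, edgeR adjusted p = 8.07e-05). Without a length correction Cox7a1 was below Cox7a2 (-0.39), Cox8b did not exceed Cox8a (-0.06) and Ldhb against Ldha lost the call (0.25, edgeR adjusted p = 0.0909); with longest transcript lengths Cox7a1 against Cox7a2 lost it (0.06, edgeR adjusted p = 0.655).

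Of the 57 pairs tested, 51 differed past the threshold, 40 with the first gene higher and 11 with the second, and 6 did not. The last pairs were Ccnd2 over Ccnd1, cyclins of the early cell cycle, at 0.56 (edgeR adjusted p = 0.00351), and the matrix genes Postn and Col1a1, which were not distinguished (0.22, 95% interval -0.25 to 0.70, edgeR adjusted p = 0.283). Postn was below Col1a1 with longest transcript lengths (-0.52, edgeR adjusted p = 0.0426) and without a length correction (-0.70, edgeR adjusted p = 0.0156).

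**Figure D2:**
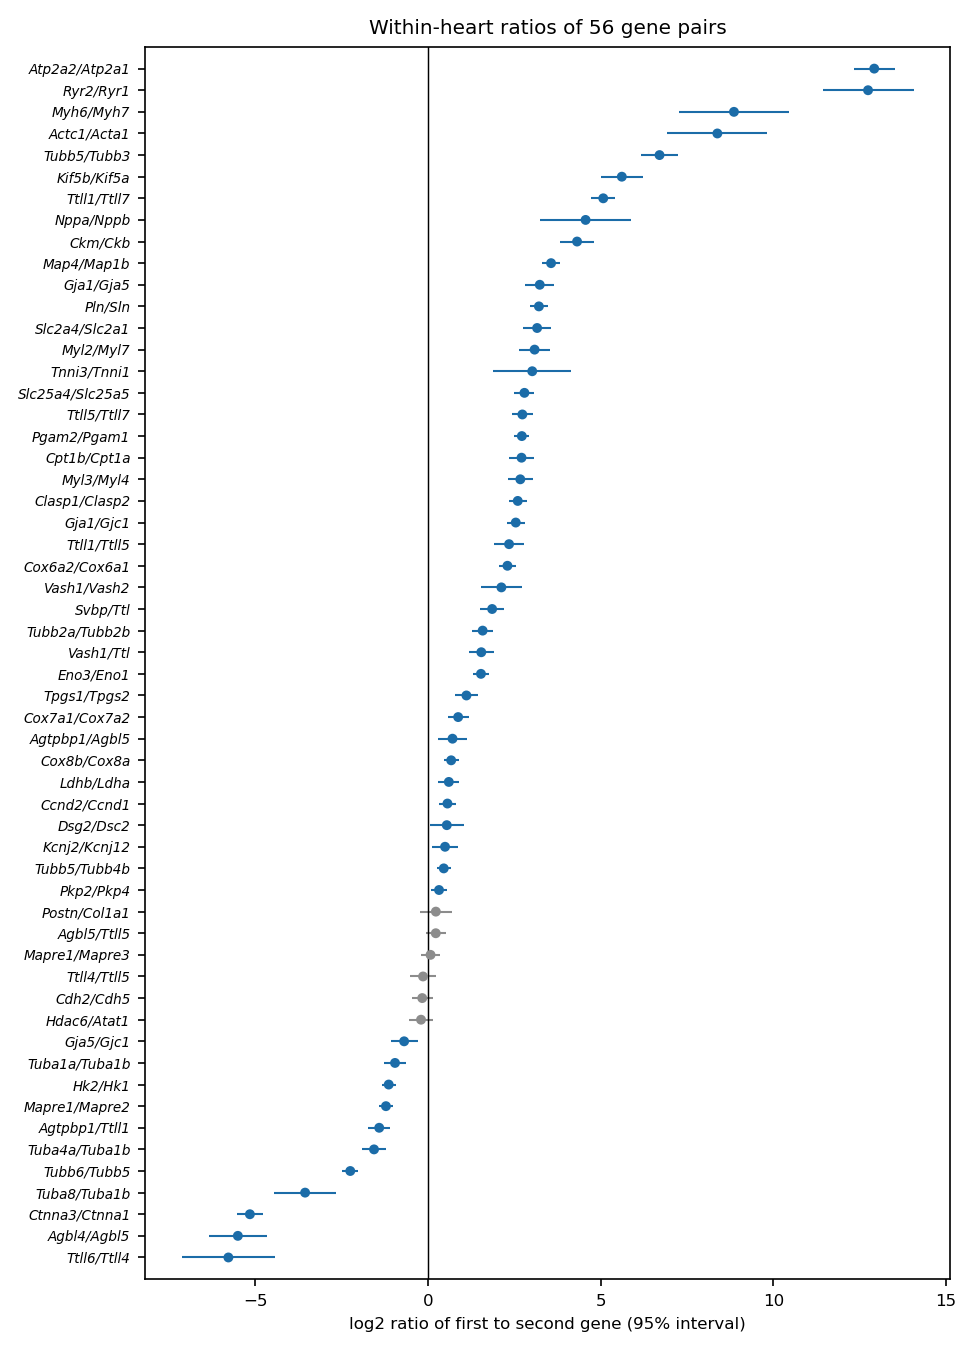
Log2 ratio of the first to the second gene of 56 of the 57 pairs within each heart (points, edgeR fit) with 95% intervals (lines) in 3 hearts, coloured where past the threshold and grey where not. Ratios ran from -5.78 for Ttll6/Ttll4 to 12.92 for Atp2a2/Atp2a1, and 50 of the pairs shown were past the threshold. Ttll6 was below the detection minimum.

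Markers of non-muscle cells ranged from high levels to near background. Endothelial markers were all detected (15 of 15), with Fabp4 at 3028 ± 44.7, Cdh5 at 255 ± 22.3, Eng at 229 ± 7.96 and Pecam1 at 229 ± 15.5 TPM. Fibroblast and matrix markers were all detected (15 of 15), with Col3a1 at 1231 ± 77.3, Postn at 782 ± 84.8, Dcn at 753 ± 25.04 and Col1a1 at 667 ± 23.2 TPM. Smooth muscle and pericyte markers (14 of 14) were led by Des, shared with cardiomyocytes, at 833 ± 65.1, Acta2 at 630 ± 309, Rgs5 at 381 ± 99.3 and Smtn at 172 ± 7.83 TPM. Of 18 macrophage and myeloid markers, 16 were detected, with Lyz2 at 78.5 ± 10.7, C1qa at 68.9 ± 8.01, C1qc at 65.9 ± 7.74 and C1qb at 61.8 ± 7.59 TPM. Lymphocyte markers were near background: 2 of 10 were detected, and the highest, the B cell gene Cd79b, was at 3.37 ± 2.03 TPM. Hba-a1, Hbb-bs, Hba-a2 and Hbb-bt, globin genes of red cells, were at 4939 ± 1285, 3355 ± 850, 3150 ± 800 and 562 ± 217 TPM, and these near-identical genes shared reads. Epicardial and mesothelial markers (12 of 12) included Upk3b at 46.4 ± 15.9, Aldh1a2 at 46.0 ± 3.73, Msln at 38.8 ± 14.7 and Krt19 at 30.5 ± 13.3 TPM. Of 12 neural and glial markers 8 were detected, among them Dbh at 6.16 ± 0.115 and S100b at 4.92 ± 1.79 TPM. Of 10 adipocyte markers 8 were detected, led by the brown fat genes Ucp1 at 207 ± 90.6 and Cidea at 103 ± 21.8 and by Fasn at 24.7 ± 6.68 and Adipoq at 21.5 ± 9.14 TPM. Atrial, conduction and valve genes (16 of 17) were led by Nppa at 3992 ± 606, Myl7 at 3102 ± 480, Myl4 at 1529 ± 168 and Sln at 458 ± 25.7 TPM.

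All 28 proliferation genes were detected, led by Cdk4 at 189 ± 4.36, Pcna at 146 ± 5.74, Ccnd2 at 105 ± 6.35 and Ccnd1 at 71.8 ± 10.8 TPM. Imprinted growth genes included Igf2, a fetal growth factor, at 680 ± 135, Mest at 233 ± 21.1, Grb10 at 132 ± 13.7 and Igf2r at 100.3 ± 19.8 TPM (8 of 8 detected). Hypoxia and injury genes (16 of 20) were led by Nppa, Ankrd1 at 807 ± 315, Sod2 at 248 ± 14.9 and Vegfa at 223 ± 29.9 TPM. Immediate early and heat shock genes (25 of 26) were led by Hspb1 at 394 ± 7.59, Klf2 at 95.004 ± 38.0, Jund at 93.8 ± 14.98 and Dusp1 at 84.4 ± 49.4 TPM. Each heart expressed the Y-linked genes Eif2s3y, Ddx3y, Uty and Kdm5d, at 105 ± 4.89, 32.2 ± 5.19, 11.1 ± 0.781 and 9.90 ± 1.15 TPM. Genes of other organs gave the background: 1 of 11 was detected, Krt14 at 4.11 ± 2.08 TPM, with Cela1 and Ins2 at 0.525 ± 0.334 and 0.191 ± 0.166 TPM. Of 19 genes of thymus, lung, liver and skeletal muscle in the table, 4 were detected in every heart: Ckm, Acta1, Tnni2 and Myh8. Scgb1a1 was at 1202, 0.280 and 3.48 TPM in hearts 1, 2 and 3.

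Beyond levels, 226 of 13519 genes tested varied between the 3 hearts more than genes of the same abundance (edgeR goodness of fit, Benjamini-Hochberg adjusted). By TPM, 111 of these were highest in heart 1, 18 in heart 2 and 97 in heart 3. Esr1, the gene of estrogen receptor alpha (ID 13982, chromosome 10, 4611989 to 5005633, plus strand), had the smallest adjusted p, with 83.8, 118 and 909 TPM in hearts 1, 2 and 3 (edgeR adjusted p = 1.37e-61). Cbr2, a carbonyl reductase of lung, was at 110.3, 9.96 and 15.9 TPM in the 3 hearts, the heart order of Scgb1a1. Genes highest in heart 3 were Nr4a1, an activity-induced receptor gene (8.19, 15.9 and 60.3 TPM), the natriuretic peptide gene Nppb (58.7, 203 and 379 TPM), Hmcn2 (0.938, 3.00 and 7.33 TPM) and Acta1 (24.7, 74.2 and 129.6 TPM). Other genes highest in heart 1 were Ltf, a neutrophil and glandular gene (11.2, 1.66 and 0.425 TPM) and Abca4 (20.02, 7.08 and 3.92 TPM). The largest adjusted p among these genes was 2.36e-17 in the edgeR test. With 1 heart left out, 99 genes were called without heart 1, 110 without heart 2 and 82 without heart 3. Of these, 64, 108 and 75 were among the 226.

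**Figure D3:**
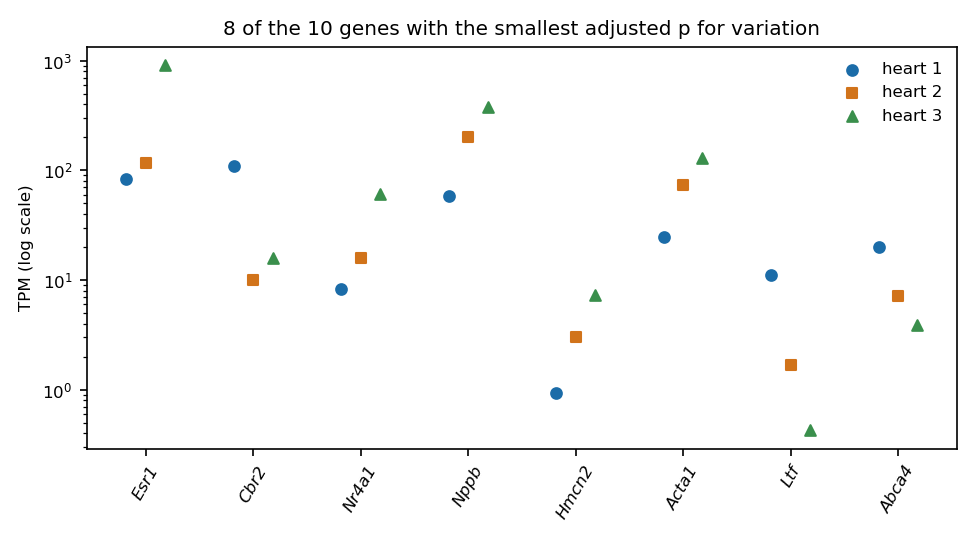
TPM (log scale) in each of the 3 hearts of 8 of the 10 genes with the smallest edgeR adjusted p for variation between hearts. Esr1 was at 909 TPM in heart 3 against 83.8 and 118 TPM in hearts 1 and 2.

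Whole gene lists were then compared with 10000 random lists of the same abundance, and 12 of 25 lists varied more than these by a permutation test. The heart in which a list member was highest was read from TMM-scaled CPM. Immediate early genes, which respond within minutes to many stimuli, and heat shock genes formed 1 list. Its members were highest in heart 3 for 26 of 26, and 11 members were variable (18 adjusted over the list alone; permutation adjusted p = 0.00125). By TPM, Myc of this list was highest in heart 1 (10.2, 8.02 and 9.72 TPM). The 11 were Btg2, Cyr61, Dusp1, Egr1, Egr3, Fos, Fosl2, Jun, Junb, Klf2 and Nr4a1, with Fos at 4.13, 6.30 and 17.9 TPM and Egr1 at 24.2, 38.6 and 76.6 TPM in hearts 1, 2 and 3. None of the 11 is a heat shock gene, and the heat shock gene Hspb1 was at 393, 387 and 402 TPM in hearts 1, 2 and 3. Adipocyte markers were highest in heart 1 for 7 of 8 members, and 5 were variable (7 adjusted over the list alone): Adipoq (29.4, 11.5 and 23.6 TPM), Plin1, Cidec, Ucp1 (301, 120 and 201 TPM) and Cfd (permutation adjusted p = 0.00125). Erythroid markers were highest in heart 2 for 7 of 10 members, and Alas2, Hbb-bt and Tfrc were variable (9 adjusted over the list alone; permutation adjusted p = 0.00125). Proliferation genes were highest in heart 2 for 16 of 28 members (permutation adjusted p = 0.00125), with 0 variable over all genes or over the list alone in the edgeR test. Mki67 was at 3100, 4102 and 2577 counts. The unadjusted permutation p behind the value of 0.00125 was 0.0002, the smallest that these permutations can give.

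Epicardial and mesothelial markers were highest in heart 1 for 9 of 12 members, with Krt19, Msln and Upk3b variable (4 adjusted over the list alone; permutation adjusted p = 0.00200). Macrophage and myeloid markers were highest in heart 1 for 14 of 16, with the neutrophil genes S100a8 (99.3, 27.4 and 6.34 TPM), S100a9 (102, 34.9 and 9.61 TPM) and Ngp variable (3 adjusted over the list alone; permutation adjusted p = 0.0155). Heart 1 was also the heart with 4096 Scgb1a1 counts. Imprinted growth genes were highest in heart 1 for 6 of 8, with Dlk1 and Plagl1 variable (3 adjusted over the list alone; permutation adjusted p = 0.00417). Smooth muscle and pericyte markers were highest in heart 3 for 10 of 14, with Acta2 (303, 670 and 918 TPM) and Tagln variable (3 adjusted over the list alone; permutation adjusted p = 0.0179). Tubulins were highest in heart 3 for 9 of 16, with Tuba8 (45.8, 90.8 and 124.8 TPM) variable (4 adjusted over the list alone; permutation adjusted p = 0.00778). Ion channel genes (Cacna1h and Kcnd2 variable), atrial, conduction and valve genes (Bmp10 variable, 3 adjusted over the list alone) and glycolysis genes (0 variable) also passed, with permutation adjusted p of 0.00625, 0.00625 and 0.0179.

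The other 13 lists did not pass. Glutamylases and their partners had 0 variable members of 9, and their variation was below that of the median random list (permutation adjusted p = 0.289). The tests of 5 lists with fewer than 5 tested members were not run, among them the deglutamylases with 0 of 4 variable and the sex-linked genes with 0 of 4. Sarcomere genes included 3 variable members, Acta1, Myh7 and Tnni1 (permutation adjusted p = 0.208), and fatty acid genes 2, of which 1 was Ucp3 (permutation adjusted p = 0.823). Nppb and Ankrd1 of the hypoxia and injury list, Mapt, Xirp2 and Vwf of their lists were variable as single genes, with permutation adjusted p for their lists between 0.203 and 0.603. Permutation adjusted p was 0.203 for thymus, lung, liver and skeletal muscle genes, 0.334 for neural and glial markers, 0.452 for fibroblast markers, 0.679 for oxidative phosphorylation, 0.941 for connexins and 0.976 for other tubulin modifiers. The immediate early list passed under all 7 settings tried, and the adipocyte, erythroid, epicardial and macrophage lists under 6 of 7. Without heart 3 the calls of the tubulins (0.479), smooth muscle markers (0.740), imprinted genes (0.372), ion channels (0.0729), glycolysis (0.0886), proliferation (0.0790) and atrial genes (0.0787) ended, all permutation adjusted p. Without heart 2 those of the adipocyte markers (0.435), tubulins (0.384), proliferation (0.0559) and macrophage markers (0.0559) ended, and without heart 1 those of glycolysis (0.867) and atrial genes (0.607), all permutation adjusted p. Without heart 1 the sarcomere genes (0.0146) and the neural and glial markers (0.0175) passed, both permutation adjusted p. With the mean in place of the median deviance, 3 of the 12 calls remained, those of the immediate early, macrophage and adipocyte lists, and 9 ended. The sarcomere genes (0.0450), the neural and glial markers (0.0183) and the thymus, lung, liver and skeletal muscle genes (0.0288) passed under that setting, all permutation adjusted p.

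**Figure D4:**
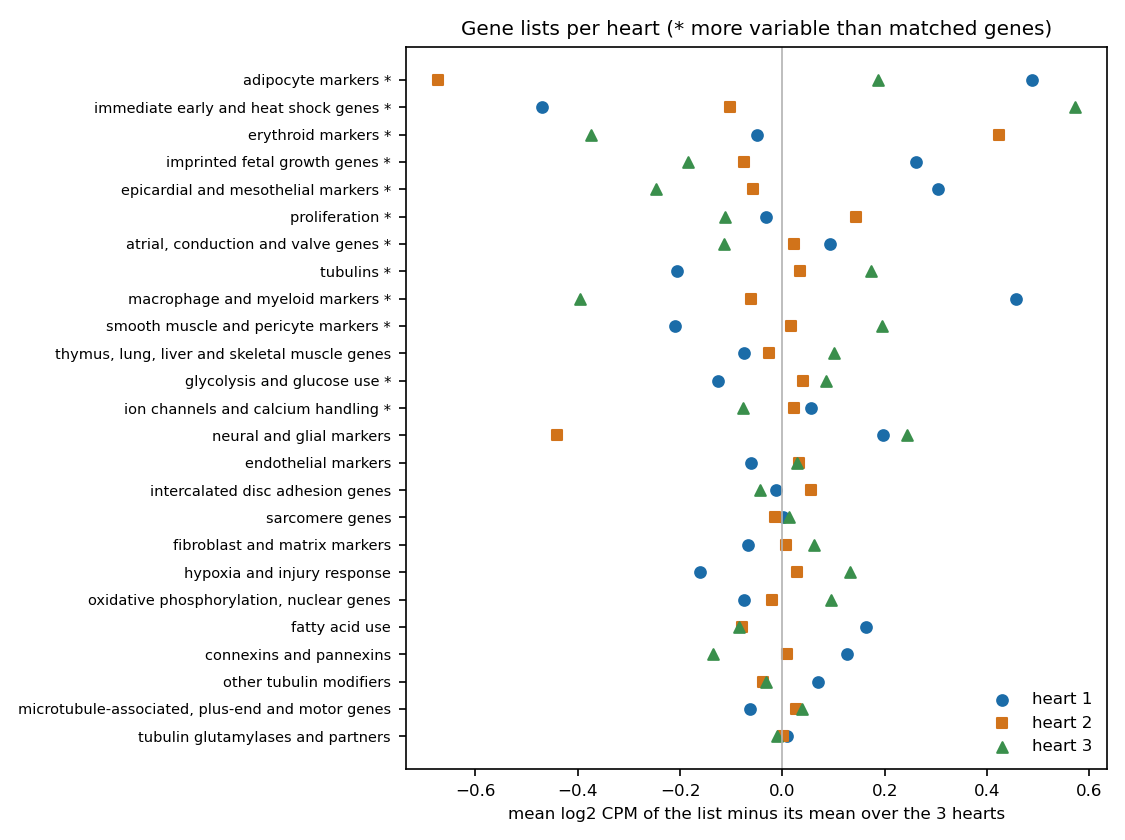
Mean log2 CPM of each gene list in each of the 3 hearts, minus the mean of that list over the hearts, for the 25 lists tested. Asterisks mark the 12 lists that varied more between hearts than random lists of the same abundance.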

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

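None of the tests here was chosen after the result was seen. Detection ranged from 12958 to 13588 genes. Among gene pairs, 57 of 57 kept direction and side of the threshold with no replicate block, DESeq2 size factors, the DESeq2 Wald test and limma, as did 54 of 54 with both genes at 10 counts or more. Leaving out a heart gave 47 to 52 pairs past the threshold, against 51. No pair changed sign in those settings, and a call can be lost there through fewer samples alone. Without a length correction 11 pairs changed sign: Cox7a1/Cox7a2 -0.39, Cox8b/Cox8a -0.06, Cdh2/Cdh5 0.12, Pkp2/Pkp4 -0.30, Ttll4/Ttll5 0.72, Agtpbp1/Ttll1 0.33, Agbl5/Ttll5 -0.20, Tpgs1/Tpgs2 -0.70, Svbp/Ttl -0.94, Hdac6/Atat1 0.48 and Postn/Col1a1 -0.70. That setting drops the length term, so the ratio moves by the ratio of the lengths. It also set the summed log2 ratios to 0.47 (glutamylases over deglutamylases), 4.48 (chain-initiating over chain-elongating) and 0.68 (alpha over beta tubulins). Longest transcript lengths turned Kcnj2/Kcnj12 to -0.29 and Postn/Col1a1 to -0.52, and added calls for Agbl5/Ttll5 (0.41), Hdac6/Atat1 (-0.83) and Mapre1/Mapre3 (0.50). Only the lengths differ in that setting, so each ratio moves by the change in the ratio of the lengths. Which lengths are nearer the truth was not tested.

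Variable genes numbered 226. Poisson deviance, which allows for counting noise alone, called 6120, and leaving out a heart called 82 to 110, with fewer samples in the test. A common dispersion called 280 (195 of the 226 among them) and no filter 256 (153 among them). DESeq2 size factors and a filter of 10 counts called 227 and 229. Lists past the threshold numbered 12. The mean deviance gave 6, of which 3 were among the 12 (immediate early, macrophage and adipocyte lists). It ended 9 calls, with permutation adjusted p of 0.0600 for erythroid, 0.0690 for imprinted, 0.0759 for epicardial, 0.0787 for smooth muscle, 0.118 for proliferation, 0.118 for tubulin, 0.131 for atrial, 0.185 for ion channel and 0.717 for glycolysis genes. It added sarcomere genes (0.0450), neural and glial markers (0.0183) and thymus, lung, liver and skeletal muscle genes (0.0288), all permutation adjusted p. Single genes with a large deviance move a mean more than a median. In the thymus, lung, liver and skeletal muscle list, Acta1 had a deviance of 108 against a list mean of 19.8, and Acta1 was highest in heart 3. The sarcomere list also holds Acta1, with Tnni1 (68.4) and Myh7 (61.3). Scgb1a1 was not among the genes tested. Leaving out a heart gave 5 to 12 lists, and without replicate 1 sarcomere genes and neural and glial markers were added. Glycolysis turned from more to less variable than random lists without replicate 1, with permutation adjusted p from 0.0313 to 0.867 over the hearts left out. Settings without mitochondrially encoded genes gave no value, since those genes were not analysed here.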

Other observations

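The tests of scaling, smooth muscle share, fatty acid response and Esr1 were chosen after the result was seen, and those of length and GC content, fat genes and airway genes before, although airway genes were looked for only after Scgb1a1 was seen and their test with no minimum of counts was added after, as were the tests of heart 1 against heart 3. The single genes in the next sentences are from the 226 that varied, were chosen after their values were seen, and stand for no wider group. Acot1, a fatty acyl thioesterase, was at 130.3, 60.8 and 49.7 TPM in hearts 1, 2 and 3, Angptl4, an inhibitor of lipoprotein lipase, at 129.7, 73.8 and 59.9 TPM, and Ucp3, a mitochondrial carrier, at 106, 71.4 and 53.6 TPM (largest edgeR adjusted p = 0.00506). Txnip, which limits glucose uptake, was at 981, 595 and 494 TPM, and Fkbp5, a glucocorticoid-induced co-chaperone, at 13.5, 7.64 and 6.36 TPM (edgeR adjusted p = 0.00723 and 0.0209). Other metabolic genes were lowest in heart 1, such as the creatine kinase gene Ckmt2 (512, 983 and 1091 TPM) and Oxct1 (133, 243 and 239 TPM). The fetal isoforms Tnni1 (1726, 862 and 448 TPM) and Myh7 (48.8, 25.5 and 14.8 TPM) were highest in heart 1. Acta1 and Nppb, which are likewise expressed in the fetal heart, were lowest there.

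Single genes highest in heart 3, also chosen after their values were seen, included H2-K1, which was at 64.6, 58.6 and 169 TPM, B2m, at 377, 362 and 766 TPM, H2-D1, at 106, 96.1 and 183 TPM, and Cd74, at 16.2, 15.8 and 37.6 TPM in hearts 1, 2 and 3 (largest edgeR adjusted p = 0.000111). H2-K1 and H2-D1 are related genes, so the division of reads between them is uncertain. Ankrd1, a stretch-responsive cardiac gene, was at 500.1, 793 and 1129 TPM, and Ctgf, a matrix regulator, at 38.5, 77.7 and 110.1 TPM.

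Immediate early and heat shock genes were higher in heart 3 than in heart 1 by a median log2 ratio of 0.93 (95% bootstrap interval 0.64 to 1.24, 26 genes). Bootstrap intervals here and below resample the genes of a list in a comparison of 1 heart with 1 heart. Such genes vary together and are not independent replicates, so the intervals are too narrow and hold no spread between hearts. A scaling difference between libraries would move all genes alike, but the list exceeded the median of all 13519 genes by 0.928. The values were already TMM-scaled, with that median at 0.004, and the list was noted for being highest in heart 3. This check could therefore hardly come out otherwise and adds no independent support. Gene length and GC content were argued against by a median of 0.929 (0.50 to 1.22) after subtracting that of genes in the same length and GC bin, for 25 genes. A larger share of smooth muscle in heart 3 was argued against as the whole cause, since smooth muscle and pericyte markers were higher by 0.319 (0.17 to 0.46). Time from death to lysis, handling and true differences between the animals remain open, and no other biological explanation was tested.

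Heart 1 may have carried airway tissue: RNA of airway tissue in heart 1 was tested with the 17 of 18 airway epithelium genes other than those first noticed that had 10 or more counts over the 3 hearts (1 of them, Lypd2, was already among the 226 variable genes). Their median log2 ratio of heart 1 to heart 2 was 3.62 (95% bootstrap interval 2.39 to 5.02), 15 of 17 were highest in heart 1, and 1 of 17 reached 1 CPM in both other hearts (with no minimum of counts the median of all 18 was 3.80, 2.54 to 4.91, and 16 of 18 were highest in heart 1; the median of 17 genes chosen after Scgb1a1 was seen was 6.65). The airway genes with the most counts in heart 1 were Scgb1a1 (4096, 1 and 13 counts), Scgb3a1 (2880, 2 and 8), Scgb3a2 (1665, 1 and 12) and Cyp2f2 (1358, 1 and 5), while the alveolar gene Sftpc had 4, 0 and 0, and the test does not tell dissected tissue from a later mixing of RNA. Fat tissue in the sampled tissue was tested with 11 fat genes outside the fixed list, which were higher in heart 1 than in heart 2 by 0.522 (0.38 to 0.58) and than in heart 3 by 0.22 (0.09 to 0.46), and 8 of 10 adipocyte markers, led by Ucp1 (301, 120 and 201 TPM) and Cidea (103 ± 21.8 TPM), were detected in every heart. The adipocyte markers mainly set heart 2 apart: 7 of 8 were lowest there, and the median log2 ratio of heart 1 to heart 3 was 0.29 (0.09 to 0.60). Without replicate 2 the list did not pass (permutation adjusted p = 0.435, range 0.00104 to 0.435 over its alternatives). A shared fatty acid response of the heart muscle was argued against only for the difference between hearts 3 and 2. Its target genes had a median log2 ratio of heart 3 to heart 2 of 0.063 (-0.23 to 0.13) against 0.87 (0.38 to 1.52) for the adipocyte markers. These targets were not compared between heart 1 and the other hearts, so such a response in heart 1 remains open. No other biological explanation was tested.

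Esr1 had 1606, 2299 and 18419 counts, a log2 ratio of 3.48 between hearts 3 and 1, while Esr2 had 2, 4 and 2, and the receptor target genes Pgr and Greb1 had 5, 2 and 0 and 11, 35 and 12 counts. Reads shared with related receptor genes were argued against, since the number of hearts with an Esr1 count that is not whole was 0. A larger share of another cell type was argued against for the 8 marker lists compared, whose highest median was 0.319, while cell types outside those lists remain open. The lymphocyte markers, with 2 tested members, were not compared. Their mean log2 CPM was 0.530, 0.740 and 1.408 in hearts 1, 2 and 3. Reads from an estrogen receptor transgene, as carried by inducible Cre strains, could give such counts, and cannot be told apart from native transcripts here: the length implied by the Esr1 counts and FPKM was 0.330 of its longest transcript, but was alike in hearts 1, 2 and 3 (0.333, 0.330 and 0.329), so it does not bear on the excess of heart 3. The labels give wild-type mice, and no other biological explanation was tested.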
